A study of Mus musculus with 3 samples.

How the data were processed

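RNA-seq was measured in pancreatic islets of male C57BL/6 mice in 3 groups with 1 library each: mice on the diet labelled ND that received DMSO by gavage (ND), mice on a high-fat diet that received DMSO (HFD_DMSO) and mice on a high-fat diet that received CGP 57380 (HFD_CGP). Per the labels' protocols, RNA was extracted with Trizol and TruSeq libraries were made from 1 ug of total RNA. The labels do not say how many animals went into each library. The aligner, the read counter, the genome build and the use of strand are not given in the sources used here. Per the submitters' processing notes, DESeq2 1.10.1 was used.

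The authors deposited a full table per pair of groups, 3 in all, and separate lists of their calls. Each full table holds a signal column per group, which the authors had made by dividing read counts by a factor per library, so that the pair shares 1 library size. The deposited log2 column gives the fold change of the first group over the second, and the deposited p-value columns give the raw p and the p adjusted by the Benjamini-Hochberg procedure over the genes of that table. Group values were scaled separately in each table, so levels were compared only within a table. All columns of per-sample values were used. An empty line in each of the full tables was not used.

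Values of lowly expressed genes were whole multiples of what 1 read is worth in that column, and the whole reads were recovered by dividing by it. Between 99.38% and 99.97% of the values of a column came out within 0.1 of a whole number, and 100% of those under 1000 reads did. The tables that share a group gave different reads for 21 genes in ND, 12 in HFD_DMSO and 21 in HFD_CGP, by at most 33 reads or 0.0027%. Recovered reads per library were 17129038 in ND, 16297537 in HFD_DMSO and 17623821 in HFD_CGP. A count of 0 allows up to 3 reads, which is 0.175, 0.184 and 0.17 CPM in the same order.

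The deposited values were matched by edgeR's exact test on the recovered reads with TMM factors and a fixed dispersion of 0.04, leaving out genes with fewer than 2 reads over the pair. This was found by recomputation and is not recorded in the labels or the file headers. With edgeR 4.0.16 the recomputed log2 fold changes differed from the deposited ones by at most 0.00029, and the calls differed for 0 genes. The recomputed p lay within 1% of the deposited p for 100%, 98.7% and 98.2% of the genes of HFD_DMSO vs ND, HFD_CGP vs HFD_DMSO and HFD_CGP vs ND. A fixed dispersion of 0.04 is a biological coefficient of variation of 0.2 that was assumed, not estimated: 1 library per group holds no information on the spread between animals. The counts of called genes are those of the authors' deposited table, at an adjusted p under 0.05, and the fold changes of single genes and lists are the recomputed ones.

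Of the 24119 gene IDs in the tables, 24079 (99.8%) were found in GENCODE M21 on GRCm38, and 22940 of these (95.3%) had the same chromosome, start, end and strand there. Coordinates are those of the deposited tables, 1-based. Symbols of list members were matched to the tables by name or, failing that, by a RefSeq synonym.

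The choices in this paragraph were made before the data were examined. The calls of the authors' deposited table were the main result, with no test of the re-analysis added, since the labels give 1 library per group. The design assumed that the deposited test was a DESeq2 comparison. The genes named were, in each comparison, the 10 protein-coding genes called higher and the 10 called lower with the largest fold change among those with at least 100 normalized counts in the higher group. From each gene list up to 4 called members with at least 100 normalized counts were added, taken by fold change. Always named were 12 genes: Ins1, Ins2, Gcg, Sst, Mknk1, Mknk2, Eif4e, Mafa, Pdx1, Ucn3, Slc2a2 and Aldh1a3. Of the genes this allowed, the text names a part, and some list members are not reported here. For each of 29 gene lists the median log2 fold change was taken over members with at least 10 normalized counts in either group and placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes the libraries and is not a p-value. For each list the called members were counted over all genes tested and again with the deposited p-values adjusted over the list alone.

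The lists covered islet cells (beta-cell identity, dedifferentiation and progenitor, beta-cell disallowed, alpha cell, delta, PP and epsilon cell, glucose sensing and insulin secretion). Lists of cell programs were unfolded protein response, MNK and eIF4F, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, glycolysis, fatty acid oxidation and lipid handling, cholesterol synthesis, cell cycle, senescence and p53, antioxidant and NRF2, inflammation and NF-kB, interferon and antigen presentation, and immediate early and heat shock. Other cell types were covered by the macrophage, lymphocyte, acinar cell, duct cell, endothelial cell, Schwann cell and neuron, adipocyte, erythrocyte, and stellate cell, fibroblast and matrix lists. The beta-cell identity and the secretion list share 3 genes, among them Slc2a2 and Glp1r, and Ldha, Hk1 and Hk2 stand in both the disallowed and the glycolysis list. The circadian clock, plasma cell and glucocorticoid response lists were added after seeing the data. Of the plasma cell list, Ighm, Igkc and Derl3 are in other lists, as are Mt1 and Mt2 of the glucocorticoid response list.

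For a named gene, a 95% counting interval of the fold was computed from the exact (Clopper-Pearson) binomial interval of the reads of the pair; shares of reads carry Wilson intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Over named genes with at least 100 reads in both libraries, the largest half-width of the interval was 0.32, 0.33 and 0.29 on the log2 scale in HFD_DMSO vs ND, HFD_CGP vs HFD_DMSO and HFD_CGP vs ND. Genes with 0 reads in 1 library are given as at least N-fold, against 3 reads there.

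Genes called in opposite directions by HFD_DMSO vs ND and HFD_CGP vs HFD_DMSO, which share the HFD_DMSO library, were set beside the overlap of independent lists and beside 25 draws of unchanged libraries per assumed spread. Alternatives fixed beforehand were an adjusted p under 0.01, an absolute log2 fold of at least 1, a minimum of 10 normalized counts, protein-coding genes alone, the authors' separate lists of calls, pseudocounts of 1 and 10, minimum means of 0 and 100, centring on the median gene and rescaling without the 20 most abundant genes. Added after seeing the data were the exact test on the recovered reads, a biological coefficient of variation of 0.1 or 0.4, DESeq2 1.42.0 size factors, TMM over all 3 libraries, library totals without TMM, a filter on low reads before TMM, a likelihood ratio test without and with a correction for transcript GC content (loess, span 0.3) or GC content and length, and random lists matched on the higher group. Leaving out replicates and fitting a dispersion were not run, since each group has 1 library.

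The recovery of reads and the test were checked on simulated counts for the real genes, with 50 genes changed at each known fold. At the assumed dispersion, 78%, 90% and 86% of genes changed 4-fold were called in HFD_DMSO vs ND (21905 genes), HFD_CGP vs HFD_DMSO (21358) and HFD_CGP vs ND (22134), 100% of those changed 8-fold, and 4%, 8% and 8% of those changed 2-fold. Of unchanged genes, 0.02% were called in each. With a true coefficient of variation of 0.4, the same test called 9.15%, 9.68% and 9.33% of unchanged genes (of 21787, 21253 and 22015 genes). List percentiles were tested on simulated data as well. Analyses used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.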

Results

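The data are mRNA profiles of pancreatic islets isolated from male C57BL/6 mice, with 1 library in each of 3 groups. ND islets came from mice on the diet labelled ND that were given DMSO by mouth, HFD_DMSO islets from mice on a high-fat diet given DMSO, and HFD_CGP islets from mice on a high-fat diet given CGP 57380. Gavage lasted 1 month. CGP 57380 is an inhibitor of the MNK kinases, which phosphorylate the cap-binding translation factor eIF4E. The libraries held 17129038 (ND), 16297537 (HFD_DMSO) and 17623821 (HFD_CGP) reads assigned to genes, with at least 1 read for 22380, 20511 and 21705 genes. Insulin transcripts took very different shares of them: Ins1 and Ins2 together made up 15.32% of the ND reads (Wilson 95% interval 15.3 to 15.33), 43.5% of the HFD_DMSO reads (43.48 to 43.52) and 19.09% of the HFD_CGP reads (19.07 to 19.11). With 1 library per group no difference has a replicate check, and each test compares the 2 libraries of a pair, not the diets or treatments. A gene is said to have risen or fallen where the adjusted p in the authors' deposited table was under 0.05. That test assumed the spread between animals. The smallest absolute log2 fold change that passed it among genes with at least 100 normalized counts was 1.04 in HFD_DMSO vs ND, 1.25 in HFD_CGP vs HFD_DMSO and 1.19 in HFD_CGP vs ND, and genes with up to 1.25, 1.47 and 1.38 did not pass. The median gene at that level stood at -0.12, 0.10 and 0.03 in the same order. Members named to complete a count of 5 or fewer were chosen after their values were seen. Gene coordinates are on GRCm38.

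HFD_DMSO vs ND addresses the effect of the diet. The insulin genes were higher in HFD_DMSO, while 7 other beta-cell identity genes were lower. Ins1 (ENSMUSG00000035804, chromosome 19, 52264323 to 52265456) rose by a log2 fold change of 3.41 (counting interval 3.40 to 3.42), from 322539 to 2246436 reads. Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) rose by 1.68 (1.68 to 1.69), and since the genes are close paralogs the split of reads between them is uncertain. Slc2a2, the glucose transporter of the beta cell (ENSMUSG00000027690, chromosome 3, 28697903 to 28731359), had a log2 fold change of -2.80 (-2.87 to -2.73), from 20546 to 1931 reads. Glp1r, the receptor of the incretin GLP-1 (ENSMUSG00000024027, chromosome 17, 30901867 to 30936510), stood at -3.75 (-4.10 to -3.43) and the zinc transporter Slc30a8 at -1.84.

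Of the 26 measured genes of the beta-cell identity list, Ins1 and Ins2 rose, 7 fell and 17 did not pass the test, with a median log2 fold change of -0.69 that lay at the 1.89th percentile of random lists, and at the 5.44th when these were matched on the higher group. The beta-cell transcription factors Mafa (-0.57) and Pdx1 (-0.38) and the maturity marker Ucn3 (0.09) did not pass, although Mafa fell after a correction for GC content (-1.68). With that correction the list had 3 genes higher and 6 lower, and a median of -0.41 at the 3.88th percentile, inside the random range. In the list of glucose sensing and insulin secretion, 9 of 31 genes fell and Pcsk1n and Ptprn rose, with a median of -0.18; after the GC correction 5 were lower and 0 higher, with Pcsk1n at 1.02 and Ptprn at 0.33. The prohormone convertase Pcsk1 stood at -2.60 and the granule protein Ptprn2 (ENSMUSG00000056553, chromosome 12, 116485720 to 117276849) at -2.98 (-3.10 to -2.85). Alpha-cell genes were also lower: 6 of 12 fell and Fxyd5 rose (1.69), with a median of -1.12 at the 0.56th percentile; over the 9 members with at least 100 normalized counts it was -0.74 at the 7.1th percentile. Among them the glucagon gene Gcg stood at -2.39 (-2.41 to -2.38), and the transcription factor Irx2 at -1.47. Sst did not pass (0.00), and of the 9 genes of the delta, PP and epsilon cell list only Ghsr fell, with a list median of -0.25, or -0.62 after the GC correction. Of 12 dedifferentiation and progenitor genes, Sox9 (5.28), Myc (2.80), Vim (2.39) and Hes1 (1.54) rose and Neurog3 and Aldh1a3 fell, the latter by 1.49 on the log2 scale (interval -2.06 to -0.97). The list median was 0.60 at the 94.5th percentile, inside the random range, and 0.06 with library totals. After the GC correction it was 0.71 at the 98.71st percentile. Whole-islet libraries do not tell which cells held these transcripts.

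Of 24 genes of the stellate cell, fibroblast and matrix list, 20 rose and 0 fell, with a median log2 fold change of 3.38 above all 10000 random lists. Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), rose by 5.80 (4.96 to 6.83), from 11 to 406 reads, and the matrix proteoglycans Dcn and Lum by 5.46 and 5.62. The gelatinase Mmp2 rose by 7.89 from 3 reads, with an interval of 6.40 to 10.24. Of 21 genes that mature beta cells keep low (the beta-cell disallowed list), 17 rose and 0 fell, with a median of 2.34 above all random lists, including Pdgfra (6.55, interval 5.05 to 8.91), Mgst1 (4.59) and Igfbp4 (4.34). Only 3 of these 21 genes reached 100 normalized counts in ND, and the libraries do not tell which cells of the islets held the transcripts. Duct-cell genes rose for 8 of 15, with a median of 1.12 at the 99.96th percentile: Krt19 rose by 3.55, Muc1 by 3.28 and Spp1, osteopontin, by 3.26. Endothelial genes rose for 9 of 14 (median 1.40, above all random lists), with Eng at 3.08 and Plvap at 1.98; 4 were called higher after the GC correction (median 0.91), and Plvap was not.

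Acinar genes moved in the other direction, unevenly. Of 30 acinar-cell genes 19 fell and 4 rose (Ptf1a, Prss1, Spink1 and Try10), with a median of -1.60 below all random lists. The elastase Cela2a (ENSMUSG00000058579, chromosome 4, 141814962 to 141826160) was 52.9-fold lower, at -5.72 (-5.87 to -5.59), and the lipase Pnlip 30.9-fold lower, at -4.95, while Spink1 was higher by 1.24. Trypsins and amylases are families of near-identical copies, so their single values are uncertain. Of smaller lists, adipocyte genes (Car3, Plin4, Fabp4 and Cdo1 rose among 6) had a median of 1.63 at the 99.2nd percentile, or 0.75 at the 91.9th over 4 members with at least 100 normalized counts. Schwann cell and neuron genes (0.94, Sox10, Cryab and Uchl1 rose among 9) and erythrocyte genes (1.32, Hba-a2, Hba-a1 and Hbb-bs among 5) had medians inside the middle 95% of random lists. Try10, Sox10, Uchl1 and Plin4 did not pass after the GC correction.

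The immune lists and the immediate early and heat shock list had higher medians in HFD_DMSO, together with the stromal, duct and endothelial markers above. Of 25 inflammation and NF-kB genes 15 rose, and the interleukin-1 genes Il1a and Il1b and the receptor gene Il1r1 fell, with a median of 1.57 at the 99.99th percentile; Il1a and Il1b did not pass after the GC correction. Lcn2, lipocalin-2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose by 7.22 (5.90 to 9.15), the adhesion molecule Vcam1 by 3.63 and the chemokine Cxcl9 by 4.53. Il1r1, chosen after its values were seen, fell from 16735 to 1275 reads (-3.10). Interferon and antigen presentation genes rose for 17 of 27 (median 1.32, above all random lists), with Isg15 at 3.56, Ifit3 at 3.17 and Irf7 at 3.13. Of 16 lymphocyte genes 13 rose and Cd79a fell, with a median of 4.03, or 3.94 with the gene that had no ND read at its bound. It was 2.03 with a pseudocount of 10 and 1.96 over 4 members with at least 100 normalized counts, since these genes were scarce: 1 of 18 reached 100 normalized counts in ND. Macrophage genes rose for 6 of 17 (median 0.83, 99.3rd percentile), with Lyz2 at 1.83 and Cd68 at 1.55. Immediate early and heat shock genes rose for 12 of 18 (median 1.24, above all random lists), with Hspb1 at 2.70 and Ier2 at 2.38; after the GC correction 5 were higher and 1 lower, with a median of 0.69 at the 99.99th percentile.

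Lists of metabolism and translation had medians between -0.79 and 1.28. The mitochondrially encoded transcripts rose for 8 of 13 (median 1.28, 99.99th percentile), with mt-Nd6 at 1.78, and for 13 after the GC correction (median 2.11). The same HFD_DMSO library stood apart in Lars2, with 39976 reads against 2983 in ND and 3184 in HFD_CGP, and in Gm23935, with 103283 against 7059 and 9328, both chosen after their values were seen. The nuclear-encoded oxidative phosphorylation list had a median of 0.08, with 10 of 52 higher and Uqcrc2, Ndufs1, Sdhd and Atp5f1 lower, and 3 higher and 1 lower after the GC correction. Cytosolic ribosomal protein genes rose for 8 of 56 with a median of 0.52, a sign that turned to -0.02 when libraries were scaled by their totals. In cholesterol synthesis 9 of 24 genes fell and Mvd, Tm7sf2 and Mvk rose (median -0.79, 0.9th percentile), with Idi1 at -3.37 and Stard4 at -2.06; after the GC correction 6 were lower and 1 higher, with a median of -0.46. In fatty acid oxidation and lipid handling (median 0.01, 25 genes) Angptl4 rose by 5.23 and Scd1 rose too, while Hadhb and Acly fell. Of the 25 MNK and eIF4F genes Mknk2 and Spry4 rose and 4 fell, among them Eif4e, Eif4a2 and Eif4g2, with a median of 0.03. Eif4e stood at -1.78 and Mknk2 at 1.25, and neither passed after the GC correction (-0.75 and 0.29), while Mknk1 did not pass at all (0.11). Unfolded protein response genes went both ways (5 of 31 higher, 6 lower, median -0.22), with Atf3 at 2.51 and the sensor Ern1 at -1.71; after the GC correction 2 were higher and 2 lower (median -0.08). Glycolysis (4 of 20 higher, Bnip3 and Pdk1 lower, median 0.22), cell cycle (Aurka higher, Ccne2, Top2a and Ccnd1 lower among 34, median -0.05), senescence and p53 (4 of 16 higher, including Cdkn1a at 1.92, Tnfrsf11b and Cdkn1b lower, median -0.22) and antioxidant genes (Gsta4 and Cat higher, Nqo1 and Sod2 lower among 21, median -0.11) lay inside the middle 95% of random lists. The medians of the oxidative phosphorylation, lipid handling, MNK and eIF4F, and glycolysis lists turned negative with library totals. After the GC correction the median of glycolysis was -0.23, that of cell cycle 0.08 and that of senescence 0.17. Of the genes named in this paragraph, Uqcrc2, Ndufs1, Sdhd, Atp5f1, Tm7sf2, Mvk, Hadhb, Spry4, Eif4a2, Eif4g2, Pdk1, Top2a, Cdkn1b, Nqo1 and Sod2 did not pass then either.

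Among the 10 protein-coding genes with the largest rise and at least 100 normalized counts, Obp2b, Dpep1, Ly6d and the water channel Aqp5 had 0 reads in ND and were at least 145-fold, 106-fold, 47.3-fold and 44.3-fold higher in HFD_DMSO. The authors' deposited table called 5911 of 22899 genes, 2888 higher and 3023 lower. This count rests on the assumed spread: it was 526 (386 higher, 140 lower) with a coefficient of variation of 0.4 in place of 0.2. Fold changes followed transcript GC content, with a median of -1.17 in the lowest of 10 equal bins of genes by GC content and 0.90 in the highest, and a Spearman correlation of 0.61 across 11253 genes, which are not independent replicates. With library totals in place of TMM the split was 1600 higher and 5677 lower, since scaling moved all log2 folds by -0.54. That shift could not turn the direction of a call, since the smallest absolute log2 fold called was 1.04. Adjusted over the list alone, 21 stellate, 19 disallowed, 19 interferon, 18 inflammation, 14 immediate early, 14 lymphocyte, 9 endothelial, 9 mitochondrially encoded, 8 duct, 7 macrophage and 4 acinar genes were higher, and 20 acinar, 9 cholesterol, 9 secretion, 7 beta-cell identity and 6 alpha-cell genes were lower; in the other lists either count moved by at most 3 genes.

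**Figure D1:**
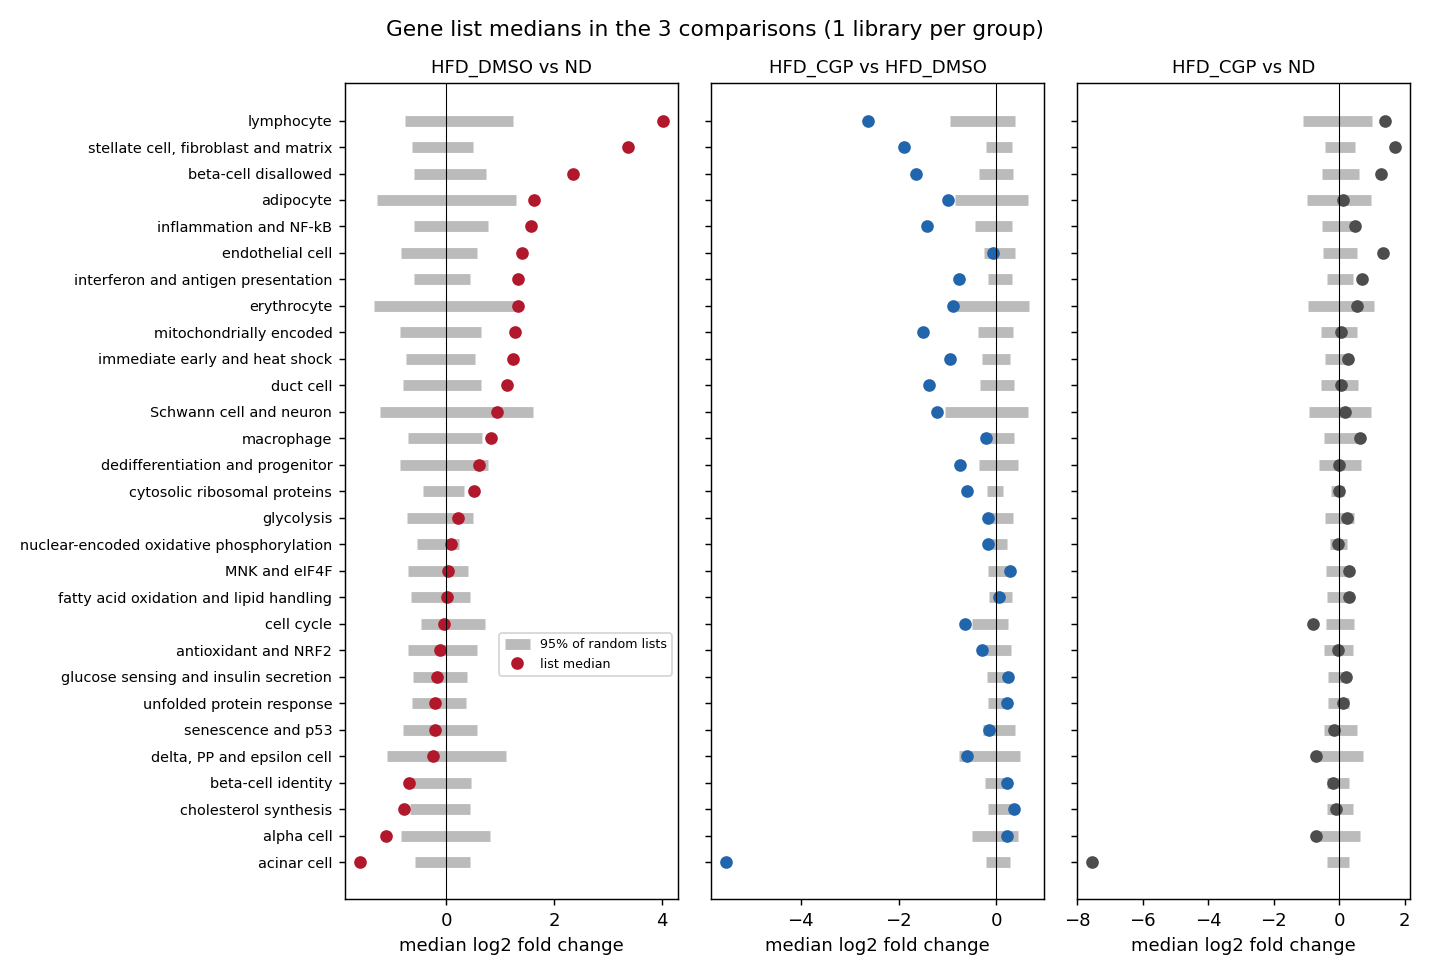
Median log2 fold change of each of the 29 gene lists (points) in the 3 comparisons, with grey bars for the central 95% of 10000 random lists matched on expression; each group has 1 library. The acinar list lay at -1.60, -5.53 and -7.55, and the stellate, fibroblast and matrix list at 3.38, -1.89 and 1.71; with library totals the points of HFD_DMSO vs ND shift by -0.54 and those of HFD_CGP vs HFD_DMSO by 0.65, which turns the sign of medians near 0, such as that of ribosomal proteins.

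**Figure D2:**
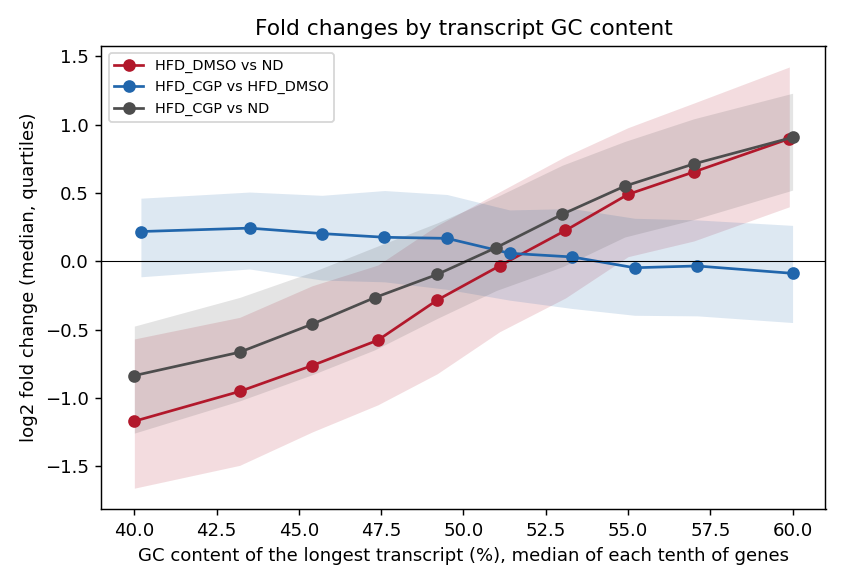
Median log2 fold change (points) and quartiles (bands) of genes with at least 100 normalized counts, in 10 equal bins of genes by GC content of the longest transcript in percent, for the 3 comparisons. Both comparisons with ND rose with GC content, from -1.17 to 0.90 and from -0.84 to 0.91, while HFD_CGP vs HFD_DMSO ran from 0.22 to -0.09.

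HFD_CGP vs HFD_DMSO addresses the effect of the kinase inhibitor on the high-fat diet. Acinar genes were far lower in HFD_CGP: 28 of 30 fell and 0 rose, with a median log2 fold change of -5.53, or -4.98 with genes lacking reads at their bound, below all random lists. The lipase-related gene Pnliprp1 (ENSMUSG00000042179, chromosome 19, 58728887 to 58744169) stood at -8.24 (-8.55 to -7.95), from 16383 to 92 reads, Reg1 at -7.96 and Try5 at -7.77. Spink1, with 3 reads in HFD_CGP, stood at -8.54 (-10.89 to -7.05), and Try10, with 0 reads there, was at least 135-fold lower. Both insulin genes fell, Ins1 by 1.92 and Ins2 by 1.81 on the log2 scale, with counting intervals no wider than 0.01 to either side.

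The other beta-cell genes mostly did not pass the test. In the beta-cell identity list Glp1r rose by 1.83 (1.48 to 2.19), only Ins1 and Ins2 fell, and the median of 26 genes was 0.23. Mafa (-0.24), Pdx1 (0.29), Ucn3 (-0.33), Slc2a2 (0.08) and Aldh1a3 (0.57) did not pass. Among 31 secretion genes Ptprn2 rose by 2.47 (2.35 to 2.60) along with Glp1r, with a list median of 0.23. Gcg (1.22) and Sst (-0.41) did not pass, and 0 of 11 alpha-cell genes did (median 0.22), while Npy fell among the 9 delta, PP and epsilon cell genes (median -0.59, and 0.06 with library totals). Of the dedifferentiation and progenitor genes Neurog3 rose and Sox9 (-3.70) and Mycl fell, with a median of -0.74 over 12, or -0.09 with library totals. The MNK and eIF4F genes, which include the targets of the compound, had 0 of 25 called and a median of 0.29: Mknk1 (ENSMUSG00000028708, chromosome 4, 115839198 to 115879250) stood at 0.41, Mknk2 (ENSMUSG00000020190, chromosome 10, 80665327 to 80678112) at -0.24 and Eif4e (ENSMUSG00000028156, chromosome 3, 138526179 to 138559696) at 0.70.

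Stromal, duct and inflammation lists had lower medians in HFD_CGP, in parallel with the acinar markers. Of 24 stellate and matrix genes 16 fell and 0 rose (median -1.89, below all random lists), with Mmp2 at -3.16, Lum at -3.15 and Col3a1 at -2.72. The beta-cell disallowed list had 12 of 21 lower and 0 higher (median -1.64), led by Mgst1 at -3.38. Of 15 duct genes 8 fell (median -1.39), among them Tff2 at -7.13, Krt19 at -4.43 (-5.11 to -3.84) and Spp1 at -2.82. Inflammation and NF-kB genes fell for 11 of 25 and only Il1r1 rose (median -1.42). Lcn2 stood at -5.51 (-6.37 to -4.78), Cxcl10 at -3.13, and Cxcl9, with 1 read in HFD_CGP, at -7.31 (-12.84 to -5.01). The medians of these lists lay below all 10000 random lists. So did that of the interferon list (9 of 27 lower, median -0.76, or -0.11 with library totals, Iigp1 at -2.40). The immediate early (5 of 18 lower, -0.95, Ier2 at -1.70) and mitochondrially encoded lists (9 of 13 lower, -1.49, mt-Nd1 at -1.65) lay there too. The last change rests on the HFD_DMSO library that stood apart in Lars2. Endothelial markers did not fall: Cldn5 rose, 0 of 15 fell and the median was -0.07, which became 0.58 with library totals.

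Lymphocyte genes split. Of 18, 9 fell, among them Ltb (-3.69), while the immunoglobulin genes Ighm and Igkc rose by 2.90 (2.61 to 3.20) and 1.72 (1.49 to 1.96). The list median of -2.62 became 0.91 over members with at least 100 normalized counts. The unfolded protein response list had a median of 0.21 over 31 genes, with Ern1 higher (441 to 2122 reads) and Atf3 lower (-2.43). In fatty acid oxidation and lipid handling (25 genes, median 0.05) Scd1 was among the genes that fell, and cholesterol synthesis (24 genes) had a median of 0.37 at the 98.4th percentile, or the 96.5th over members with at least 100 normalized counts. Cell cycle genes had Mki67 (90 to 38 reads), Ccnb1, Cenpf and Birc5 lower among 34, with a median of -0.65 that was 0.00 with library totals. Ribosomal protein genes (56 genes, median -0.61) and nuclear-encoded oxidative phosphorylation genes (52, -0.18) had 0 calls and low medians, at 0.04 and 0.47 with library totals. In the remaining lists Pgam1 rose and Aldoc fell (glycolysis, median -0.17), Gsta4 (antioxidant, -0.29), Cd14 (macrophage, -0.20), Cryab (Schwann cell, -1.21), Car3 and Cdo1 (adipocyte, -0.99) and Hba-a2 (erythrocyte, -0.88) fell, and 0 of 16 senescence genes passed (-0.14). The medians of the glycolysis, antioxidant, macrophage and senescence lists turned positive with library totals.

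The largest rise among protein-coding genes with at least 100 normalized counts was that of Asb4 (ENSMUSG00000042607, chromosome 6, 5383386 to 5433022), at 3.55 (2.49 to 4.91), followed by Pik3r2 at 3.36, Thtpa at 2.88 and the S6 kinase gene Rps6kb2 at 2.65. The authors' deposited table called 1411 of 22208 genes, 311 higher and 1100 lower. With a coefficient of variation of 0.4 the count was 171 (9 higher, 162 lower), with 0.1 it was 4671 (2084 higher, 2587 lower), and with library totals 3888, of which 3209 were higher and 679 lower, since scaling moved all folds by 0.65. Adjusted over the list alone, 29 acinar, 17 stellate, 16 disallowed, 14 inflammation, 14 lymphocyte, 11 mitochondrially encoded, 10 duct, 10 immediate early and 10 interferon genes were lower; in the other lists either count moved by at most 2 genes.

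HFD_CGP vs ND compares the treated islets with the diet control. Slc2a2 stood at a log2 fold change of -2.63 (-2.68 to -2.58), Pcsk1 at -2.28 and Glp1r at -1.84, while Ins1 was higher by 1.58 and Ins2 did not pass (-0.03). The beta-cell identity list had Ins1 higher and Slc2a2, Glp1r, Trpm5 (-1.37) and Slc30a8 lower among 26, with a median of -0.18. In the secretion list (31 genes, median 0.20) Pcsk1n (1.74) and Ptprn rose and Slc2a2, Pcsk1 and Glp1r fell. Mafa (-0.72, and -1.74 with a call after the GC correction), Pdx1 (-0.00), Ucn3 (-0.16), Gcg (-1.09), Sst (-0.32) and Aldh1a3 (-0.83) did not pass. Alpha-cell genes had 0 of 12 called with a median of -0.71 at the 1.01st percentile, or -0.53 at the 4.62nd over 9 members with at least 100 normalized counts, and of 8 delta, PP and epsilon cell genes Npy and Ghsr fell (median -0.71). After the GC correction Slc30a8, Pcsk1n, Ptprn and Ghsr did not pass, 2 alpha-cell genes were lower and the median of the secretion list was -0.04.

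Acinar genes were far lower in this pair as well: 27 of 28 fell and 0 rose, with a median of -7.55, or -7.46 with bounds, below all random lists. Cela2a was 456-fold lower (interval -9.17 to -8.52 on the log2 scale) and Pnlip 295-fold lower, and Prss3, Try10, Erp27 and Aqp12 had 0 reads in HFD_CGP and were at least 62.8-fold, 58.6-fold, 45.7-fold and 40.8-fold lower. Stellate and matrix genes were higher than in ND, with 14 of 24 up and 0 down (median 1.71, above all random lists): Col1a1 rose by 3.83 (2.97 to 4.88) and Dcn by 3.40. Endothelial genes rose for 9 of 15 (median 1.33, above all random lists), with Eng at 2.77, Plvap at 2.22 and Flt1 at 1.77, and 4 were higher after the GC correction. The disallowed list had 6 of 21 higher (median 1.29, above all random lists), led by Pdgfra and Igfbp4. Duct genes had only Tff2 called, lower, with a median of 0.07 over 13, or -0.215 after the GC correction. Mitochondrially encoded genes had 0 of 13 called with a median of 0.05, but 2 called higher with a median of 0.89 above all random lists after the GC correction. Among protein-coding genes with at least 100 normalized counts Gpnmb, a glycoprotein of macrophages and other cells (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), had the largest rise, from 3 to 204 reads (interval 4.45 to 8.31), followed by Serpina3n, the complement gene C7 and Gdf10.

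Interferon and antigen presentation genes rose for 6 of 27 (median 0.71, 99.95th percentile), including the class II genes Cd74 (1.77) and H2-Ab1 (1.59), which did not pass after the GC correction (1.14 and 0.91). Of 8 lymphocyte genes Igkc (4.66, interval 4.20 to 5.17) and Ighm (4.06) rose and Cd79a fell (median 1.40, or 0.61 with a pseudocount of 10, inside the random range). Macrophage genes had only Cd68 higher (median 0.64 over 18, 98.6th percentile, or the 94.3rd over 15 members with at least 100 normalized counts). Inflammation genes rose for 6 of 22 with Il1b lower (median 0.49, 95.5th percentile), and for 3 with 0 lower after the GC correction. Cell cycle genes fell for 7 of 35 and rose for 0, with a median of -0.80 below all random lists, Top2a at -2.17 and Mki67 at -1.99; 4 were lower after the GC correction (median -0.53), and the median was -0.22 over members with at least 100 normalized counts. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.36 in a senescence and p53 list with Bbc3 higher, Tnfrsf11b and Trp53inp1 lower and a median of -0.16 over 16. After the GC correction Cd68 (1.13), Il1b (-1.09), Bbc3, Tnfrsf11b and Trp53inp1 did not pass.

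Among the MNK and eIF4F genes the eIF4E-binding proteins Eif4ebp1 (1.47) and Eif4ebp2 (1.27) rose, and Mknk1 (1415 normalized counts in HFD_CGP against 927 in ND), Mknk2 (1051 against 489) and Eif4e (1148 against 2292) did not pass; the median of 25 was 0.29. The unfolded protein response genes Chac1 (2.13), Trib3 and Sesn2 rose among 31 (median 0.12), and the lipid genes that rose among 25 (median 0.31) included Angptl4 (4.23) and Ucp2. The genes that fell among 24 cholesterol genes (median -0.11) included Idi1 (-2.23) and Hsd17b7, and Mvd rose. Other lists had few calls: Txnip fell (antioxidant, median -0.04 over 21), Myc and Vim rose (dedifferentiation, -0.01 over 12), Rplp2 rose (ribosomal, -0.01 over 56, with both medians at 0.01 under library totals), Uqcrc1 and Atp5d rose and Ndufs1 fell (oxidative phosphorylation, -0.03 over 52), and Hspb1 rose (immediate early, 0.28 over 18). Likewise Fabp4 rose (adipocyte, 0.12 over 5), Uchl1 rose and Prph and S100b fell (Schwann cell and neuron, 0.18 over 6), and 0 of 20 glycolysis genes (0.24) and 0 of 5 erythrocyte genes (0.55) passed. After the GC correction the calls of Eif4ebp2, Trib3 (0.81), Sesn2 (0.44), Ucp2 (0.79), Hsd17b7 (-1.28), Mvd, Vim, Rplp2 and Uchl1 ended, and 0 of 52 oxidative phosphorylation genes were called. The medians then were -0.26 for the immediate early list, -0.10 for glycolysis, -0.10 for erythrocyte genes, -0.03 for the unfolded protein response, and -0.32 for cholesterol synthesis, at the 0.82nd percentile.

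The authors' deposited table called 2060 of 23063 genes, 1054 higher and 1006 lower. With a coefficient of variation of 0.4 it was 81 (27 higher, 54 lower). A likelihood ratio test gave 2698 without and 1176 with the GC correction, which the Spearman correlation of 0.70 between fold and GC content over 11387 genes prompted. Adjusted over the list alone, 18 stellate, 10 endothelial, 10 interferon, 7 inflammation, 6 disallowed and 6 MNK and eIF4F genes were higher and 27 acinar and 9 cell cycle genes lower; in the other lists either count moved by at most 2 genes.

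Setting the comparisons side by side asks whether treatment moved the genes that differed with diet. Of 21216 genes tested in both, 1120 were called in opposite directions by HFD_DMSO vs ND and HFD_CGP vs HFD_DMSO, 907 of them higher and then lower and 213 lower and then higher. Only 28 were called in the same direction, 3 higher and 25 lower in both. Genes higher and then lower included Clic6 (6.19 and -7.24), Lcn2 (7.22 and -5.51), Gabrp (6.90 and -5.32) and the mucin gene Muc6 (4.80 and -6.09), with Ins1 and Ins2 among the abundant ones. Genes lower and then higher included Ptprn2 (-2.98 and 2.47), Thtpa (-3.34 and 2.88), Sumo2 (-3.88 and 2.31) and Dnajc6 (-3.25 and 2.11). These genes, other than those of the naming rule, were chosen by the size of both folds after their values were seen.

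Independent lists of these sizes would share 191.4 genes in opposite directions and 193.6 in the same one. The shared HFD_DMSO library gives opposite signs by chance, and unchanged libraries simulated with a coefficient of variation of 0.2 gave 0 opposite genes, with 0.4 a median of 572 and at most 604. At 0.2 the draws called a median of 0 genes in each comparison, so no overlap was possible. At 0.4 the medians called were 1965 and 1975, against 5911 and 1411 in the deposited comparisons. Neither count is therefore an expectation for lists of the deposited sizes. The covariance of the fold changes over 10858 genes was -0.679, against -0.094 and -0.377 in those simulations, which leaves -0.585 and -0.302. The Pearson correlation was -0.66, against -0.50 simulated, across genes that are not independent replicates. The Spearman correlation was -0.70 and has no simulated value beside it. With 1 library in each group the shared library cannot be split, so some or all of the excess may come from it.

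**Figure D3:**
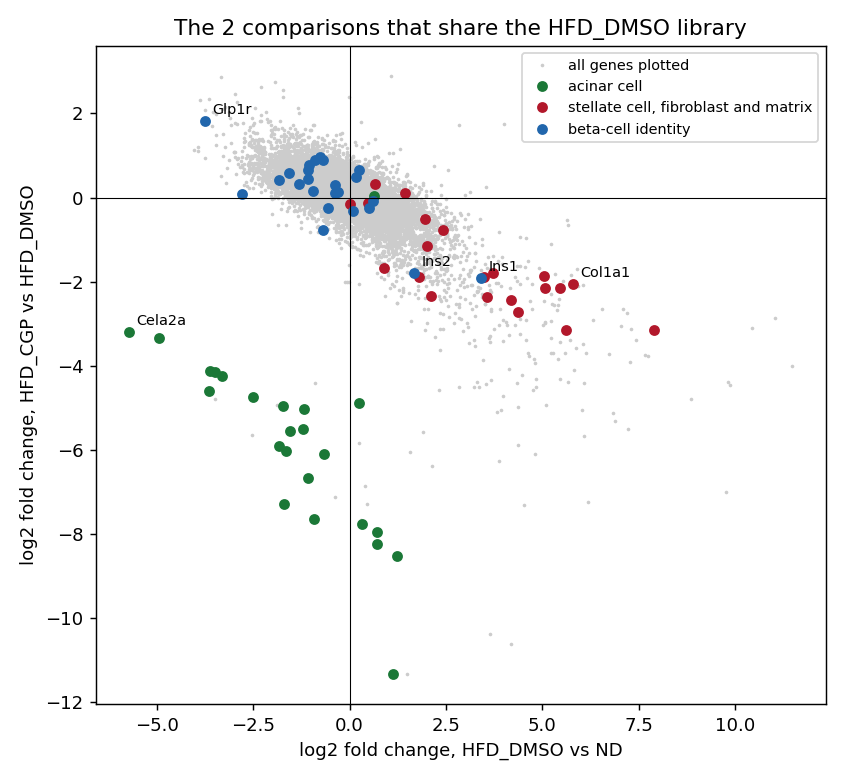
Log2 fold change of HFD_DMSO vs ND (horizontal) against HFD_CGP vs HFD_DMSO (vertical), 1 point per gene, with acinar, stellate and matrix, and beta-cell identity genes coloured; both axes share the HFD_DMSO library, which alone tilts the cloud downward. Stellate and matrix genes lie mostly at the lower right (Col1a1 at 5.80 and -2.05), and acinar genes mostly at the lower left (Cela2a at -5.72 and -3.20).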

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

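The adjusted p of 0.01, the minimum fold and counts, protein-coding genes alone, the authors' separate lists, pseudocounts, centring and rescaling without the 20 most abundant genes were fixed beforehand. All other alternatives were chosen only after the results were seen. The number of genes called rests on the assumed spread more than on any other choice tried. At a coefficient of variation of 0.1 it was 10097 in HFD_DMSO vs ND, 4671 in HFD_CGP vs HFD_DMSO and 7475 in HFD_CGP vs ND, and at 0.4 it was 526, 171 and 81, with 73.4%, 5.3% and 33.3% of them higher against 48.9%, 22% and 51.2% at 0.2. At 0.1, 44.6% of the HFD_CGP vs HFD_DMSO calls were higher. An adjusted p under 0.01 gave 3693, 836 and 946. Library totals gave 3888 in HFD_CGP vs HFD_DMSO, 82.5% of them higher, and 7277 in HFD_DMSO vs ND, 22% higher. The GC correction, made in a likelihood ratio test, gave 1176 calls in HFD_CGP vs ND and 1154 with length added, and in HFD_DMSO vs ND 4709, of which 58.9% were higher. Of the genes that test called without the correction, 3623 of 6832, 1907 of 2038 and 896 of 2698 were kept in HFD_DMSO vs ND, HFD_CGP vs HFD_DMSO and HFD_CGP vs ND. With GC content and length corrected, 3528, 1704 and 881 were kept in the same order. The calls higher in HFD_CGP vs HFD_DMSO numbered 474 in the likelihood ratio test and 561 with GC content and length corrected, against 311. All other totals of calls stayed within 1.5 times the main ones, and a minimum absolute log2 fold of 1 and the authors' separate lists changed none. Genes called in opposite directions numbered 645 at an adjusted p under 0.01, 488 among genes with at least 100 normalized counts, 99 at a coefficient of variation of 0.4 and in the likelihood ratio test 1518 without and 1479 with the GC correction. Among genes with at least 100 normalized counts fewer genes are counted by construction; the cause of the other changes was not tested.

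Of the 87 list medians, 42 lay outside the central 95% of random lists, 38 to 43 under the alternatives without a GC correction and 51 with it. The lymphocyte median in HFD_CGP vs HFD_DMSO was 0.91 over members with at least 100 normalized counts in place of -2.62, since Ighm and Igkc are among the few that remain. With the GC correction 76 list medians stayed inside or outside the central range as before, 10 moved outside it and the beta-cell identity list of HFD_DMSO vs ND moved inside it (-0.41). Some medians that stayed inside changed sign, such as that of glycolysis in HFD_DMSO vs ND (0.22 to -0.23). Of the 290 values of named genes, 265 were calls. After the GC correction 233 of the 290 values kept their status as called or not called, though the size of the folds changed. Of the calls 55 were lost, and Mafa gained a call in both comparisons with ND. Centring and a pseudocount of 1 leave the deposited p-values untouched, so they could change none of the calls. No fit without a replicate and no fit of the spread could be run with 1 library per group, and no paired analysis was possible because each group holds 1 library. Depth limits genes with few reads: over named genes with a read in both libraries the half-width of the counting interval reached 3.91 on the log2 scale.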

Other observations

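Tests of the pattern with GC content were fixed before their results were seen for the long non-coding genes and for the genes alike in both high-fat libraries, as was the test of small fold changes; the others, and the plasma cell, glucocorticoid response and circadian clock lists and all genes of the next 2 paragraphs, were chosen only after the results were seen.

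Several immunoglobulin genes had the most reads in HFD_CGP. Of 8 plasma cell genes 5 rose and Ighg1 fell in HFD_CGP vs ND, with a median log2 fold change of 3.74, while Ighg2b, Ighm, Jchain and Igkc rose in HFD_CGP vs HFD_DMSO (median 0.58 over 8). The reads of Ighm numbered 76 in ND, 105 in HFD_DMSO and 1330 in HFD_CGP, those of Igkc 38, 180 and 1009, those of Jchain 11, 21 and 173, and those of Ighg2b 0, 3 and 226. In HFD_DMSO vs ND Igha, Igkc and Mzb1 rose and Ighg1 fell among 7 genes (median 1.53). Igha did not follow, with 13, 186 and 164 reads in ND, HFD_DMSO and HFD_CGP. Immunoglobulin constant-region genes are similar in sequence and can share reads, so the split between Ighg1 and Ighg2b is uncertain.

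Glucocorticoid-responsive genes were higher in HFD_CGP than in ND for Cebpd (2.48), Zbtb16 (2.22) and Fkbp5 (1.63), with a median of 0.65 over 11 genes. In HFD_CGP vs HFD_DMSO Cebpd rose by 2.40 and Sult1a1 fell (median -0.21), and in HFD_DMSO vs ND Sult1a1, Zbtb16 and Tsc22d3 rose and Klf9 fell (median 0.66). Of 16 clock genes Npas2, Cry2 and Nfil3 rose and Nr1d2, Clock and Dbp fell in HFD_CGP vs ND (median -0.12; after the GC correction 1 was higher and 1 lower), only Npas2 rose in HFD_CGP vs HFD_DMSO (median 0.21), and in HFD_DMSO vs ND Nfil3 and Ciart rose and Nr1d2 and Clock fell (median -0.25). Il1r1, the interleukin-1 receptor, had 16735 reads in ND, 1275 in HFD_DMSO and 8020 in HFD_CGP.

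Fold changes of both high-fat libraries against ND followed transcript GC content, with Spearman correlations of 0.61 and 0.70, while HFD_CGP vs HFD_DMSO gave -0.18. A different mixture of cell types in the ND islets stays open: without genes that differ by more than 0.5 between the high-fat libraries, the correlation in HFD_CGP vs ND was 0.74 over 7552 genes, but the bound of 0.5 set beforehand was wrongly set, since that filter keeps genes by which ND differs from both (endothelial medians of 1.40, 1.33 and -0.07). A GC bias of library preparation or sequencing also stays open, since the correlation over 604 long non-coding genes was 0.25, between the bounds of 0.3 and 0.2 set for and against it, and 0.16 over 316 lincRNA genes. The diet itself cannot be told apart from the single ND library (0.7 in HFD_CGP vs ND). The trend may therefore be technical or biological, and 3623 of 6832 calls of HFD_DMSO vs ND were kept when it was removed. Fold changes also varied with transcript length. The Spearman correlations with length were -0.25 in HFD_DMSO vs ND, 0.31 in HFD_CGP vs HFD_DMSO and -0.12 in HFD_CGP vs ND. In HFD_CGP vs HFD_DMSO the trend with length was thus stronger than that with GC content, and its cause was not tested.

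Acinar transcripts differed between all 3 libraries. Between HFD_DMSO and ND, a different share of acinar tissue alone would move all members alike. The log2 folds of 23 members with at least 1000 reads had a standard deviation of 2.1. Before scaling, Cela2a had 34472 reads in ND and 427 in HFD_DMSO, and Pnliprp1 had 15357 and 16383. In the normalized values of this pair 1 read was worth 1.24 in HFD_DMSO and 0.81 in ND. The condition written against this share as the whole cause also asked for calls in both directions. Among the 23 members 18 fell and 0 rose, so it was not met there, and only all 30 members included 4 that rose. The members also include trypsin and amylase copies with uncertain single values. Cela2a, Pnlip and Pnliprp1 are not such copies. Cela2a stood at -5.72 (counting interval -5.87 to -5.59) and Pnlip at -4.95 (-5.06 to -4.84), while Pnliprp1 had no fewer reads in HFD_DMSO. With the spread of 2.1, this argues against a different share as the whole cause for the 23 members. A different share as a part of the cause stays open. The GC trend is argued against as the cause of the difference. With the correction 18 of 30 members were called lower and 4 higher, Reg1 in place of Try10 among the latter (17 and 1 of the 23). The standard deviation was then 2.06. Less acinar tissue carried over into the HFD_CGP preparation stays a candidate explanation for the lower acinar genes there: 0 members rose in either comparison of HFD_CGP, and 28 of 30 and 27 of 28 fell. The test was not met in full because Bhlha15, which other secretory cells can express, fell in neither comparison and Amy2 did not pass in HFD_CGP vs HFD_DMSO, and treatment itself cannot be told apart from the single preparation.

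Genes higher in HFD_DMSO than in ND were often lower in HFD_CGP, with 1120 genes called in opposite directions. Dilution by more non-endocrine tissue in HFD_DMSO would lower the share of Ins1 and Ins2. They held 43.5% of its reads, more than in ND or HFD_CGP, so such dilution was not the source of their rise. That follows from the rise itself and does not tell whether HFD_DMSO held more non-endocrine tissue. Other differences in tissue make-up were not tested for Ins1 and Ins2. For stromal, duct and lymphoid tissue as the sole source, the covariance of the GC-corrected folds over 14450 genes with small changes between the high-fat libraries was -0.242, lower than any simulated value (-0.112 at a coefficient of variation of 0.2 and -0.157 at 0.4); this met the bound written beforehand, but that bound moves with an assumed spread that 1 library per group cannot give, so it was wrongly set and the explanation stays open. A deviation of the single HFD_DMSO library in RNA quality or ribosomal RNA also stays open: Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, stood at 4.36 in HFD_DMSO vs ND, with 2983, 39976 and 3184 reads in ND, HFD_DMSO and HFD_CGP, the ribosomal RNA gene CT010467.1 had 49026, 162613 and 77033, and Gm23935 7059, 103283 and 9328. That the drug moved diet-changed genes back could not be separated from such a deviation, since the same 1120 genes rest on 1 HFD_DMSO library.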
